A study of Caenorhabditis elegans with 2 samples.

How the data were processed

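Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Caenorhabditis elegans hermaphrodites at the L4 larval stage. The worms carried a transgene that makes the transcription factor HLH-30 with a GFP and FLAG tag, and the chromatin was pulled down with an antibody against GFP. The labels describe 2 biological replicates from separate biosamples of strain OP433, both in 1 group, so the series holds no comparison of conditions. The chromatin was sheared by sonication, per the labels. The read alignments, the control library and the signal tracks were not used here.

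The files used were peak lists in narrowPeak format, on the builds ce11 and ce10. Per the text deposited with each sample, the authors called peaks against a control alignment for replicate 1, for replicate 2 and for both replicates pooled, and these lists hold peaks and background together. From these 3 lists they made 1 thresholded list with the irreproducible discovery rate (IDR), which keeps peaks whose ranks hold up between replicates. The peak caller, the aligner and the IDR threshold are not given in the sources used here. The deposited signal value of each peak is the authors' own score of strength on a scale that is not stated. It is used only to rank and describe peaks within a list. The deposited −log10 q-value was equal for all 7168 thresholded peaks on ce11, at 4.30, so it could not rank them and was not used further. Every list other than the thresholded ones held exactly 30000 entries. All 7168 thresholded peaks were entries of the pooled list, and they were its 7168 entries with the highest signal value, so the list is a signal cut of the pooled calls. The pooled signal value of a thresholded peak was close to the sum of the replicate values, with a median ratio of 0.998. The files hold no read counts, so the depth behind each peak is unknown. The intervals given below are 95% Wilson intervals on shares of genes or peaks and cover counting error only.

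Peak positions on ce11 were joined to the WBcel235 assembly, which is ce11, with Ensembl annotation release 115 and its 19973 protein-coding genes on the 6 nuclear chromosomes. Lists on ce10 were compared only by number, overlap and signal, and no coordinate was converted. A peak was placed by its summit. A promoter window ran from 1000 bp upstream to 200 bp downstream of each annotated 5′ end of a protein-coding transcript, and a gene counted as occupied if any of its windows held a summit. A summit in several windows counted for each gene. A summit outside promoters was placed, in this order, in a 5′ UTR, coding exon, 3′ UTR, intron, noncoding RNA or pseudogene exon, or between genes. Many C. elegans transcripts are trans-spliced, so an annotated 5′ end need not be the start of transcription. No read was recounted, so strand and multi-mapping choices of the authors carry over.

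The replicate lists hold background, so the strongest 7168 peaks of each replicate, as many as in the thresholded list, stood for that replicate alone. Placement was compared with 100 random placements within chromosomes (bedtools 2.31.1 shuffle), where the smallest p is 0.0099 one-sided and 0.0198 two-sided. Each of 18 gene lists was tested against all other protein-coding genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. The lists covered autophagy, the vacuolar ATPase, lysosomal hydrolases and membrane proteins, TOR and AMPK signalling, lipid metabolism, immune effectors, stress response and longevity, basic helix-loop-helix (bHLH) factors and leucine-zipper partners, ribosomal proteins, the proteasome, the mitochondrial respiratory chain, chemoreceptors, and markers of intestine, body muscle, pharynx, neurons, epidermis and cuticle, and germline. In all, 5 list names matched no gene name and were left out, and 4 genes stood in 2 or more lists. The same test was run on 175 gene classes with at least 10 members, a class being the letters before the hyphen of a gene name. Genes are not independent replicates, and neighbours can share a peak.

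Sequence was read in windows of 50 bp on each side of the summit and in control windows of the same size centred 500 bp to the left. Presence of a hexamer on either strand was compared within peaks by an exact McNemar test. The 10 forms of the E-box, CANNTG, were adjusted together, and the 2080 hexamers, with reverse complements joined, were adjusted in a separate scan. The peaks were divided into 5 equal parts by signal value. All tests were made in Python 3.11.15 with scipy 1.17.1. They were tested on simulated data first. For gene sets of 30 genes with planted peaks, 20 of 20 were recovered and 1 of 180 unplanted sets was called, over 19973 genes. The planted excess was large and the other peaks were placed at random, so weaker effects and clustered peaks were not tried. For the site test, a share of 9.7% planted in simulated windows for 7168 peaks was recovered as a difference of 9.84 percentage points. The simulated windows lay at random positions, so a shift in base composition between summit and control windows was not tried.

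The design, the gene lists and these alternatives were fixed before the data were examined. They were the other build, merged peaks, other overlap rules, narrower and wider promoter windows, the nearest gene only, the 3584 strongest peaks, each replicate alone, lists matched on upstream distance, other motif and control windows, 10 equal parts of the peaks, promoter peaks only, the X share of genes and other region sizes. The nearest gene was the one with the closest 5′ end at any distance, so summits outside promoter windows counted too. Using only peaks with CACGTG or CACATG, and the same alternatives for CACATG, were added after the data were seen. The named genes were chosen by rule: hlh-30 and unc-119, the genes in whose promoter windows the 10 strongest peaks fell, the 4 members of each list with the strongest promoter peak, and the 2 members with the strongest promoter peak of each of the 5 gene classes with the smallest p. Outside this rule, epg-9, aakg-3, F07H5.13, C30E1.4 and pcn-1 were named after their values were seen. A peak that the text describes lay in or near each of them. As the rule allows, fewer members were named for some lists that did not pass, and 1 chemoreceptor gene is not reported here. With 1 group of 2 samples, no test compares samples, and p-values refer to genes, peaks or placements.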

Results

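HLH-30 is a basic helix-loop-helix leucine-zipper transcription factor, the C. elegans counterpart of mammalian TFEB, a regulator of autophagy and lysosome genes. Its tagged form was mapped by ChIP-seq in L4 hermaphrodites in 2 biological replicates. The thresholded list held 7168 peaks on ce11, with a median width of 350 bp, and covered 2.2% of the nuclear genome. Signal values ran from 31.9 to 1388, with a median of 61.8. Merging peaks that overlap left 7048 regions. On ce10 the list held 7179 peaks. Read depth is unknown, since the files hold no counts.

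The first question was whether both replicates recovered the same sites. Of the 7168 strongest peaks of replicate 1, 5734 (79.99%) overlapped one of the 7168 strongest of replicate 2 by at least 1 bp, and 80.1% did so in the other direction. Random placement gave 4.68% on average and at most 5.48% (permutation test by random placement, one-sided p = 0.0099, the smallest that 100 placements can give). Across the overlapping peaks, which are not independent replicates, signal values of both replicates had a Spearman's rho of 0.79. The 3 strongest peaks were the same in both replicates and in the same order. Of the genes with a promoter peak, 4027 in replicate 1 and 4000 in replicate 2, 3359 were shared. In the thresholded list, 5515 peaks (76.9%) were among the strongest 7168 of each replicate. The ratio of signal values between replicates had a median of 1.00 and exceeded 2 in favour of replicate 1 for 5.04% of peaks and in favour of replicate 2 for 5.96%.

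Several of the strongest peaks lay at autophagy genes. The highest signal value, 1388, was inside an intron of epg-9, a member of the autophagy list whose product belongs to the complex that starts autophagy (chromosome IV, 2601898 to 2602418). Its signal value was 719 in replicate 1 and 675 in replicate 2. A separate peak of signal 168 lay in a promoter window of the same gene. The promoter of lgg-2, which encodes an Atg8-like protein of the autophagosome membrane, held the sixth strongest peak (chromosome IV, 10935975 to 10936401). Its summit was 281 bp upstream of the 5′ end, with a pooled signal of 877. The signal values in replicates 1 and 2 were 470 and 407, or 438 ± 44.9 (SD, n = 2). The promoter of lgg-1 (WBGene00002980), the other Atg8 homologue, held the ninth (chromosome II, 6348394 to 6348800), 883 bp upstream, with a pooled signal of 696. Its replicate values were 371 and 323, or 347 ± 33.8 (SD, n = 2). Single signal values given for a peak below are pooled values. The remaining promoters among the 10 strongest peaks were those of tasp-1 and K01G5.10, which share a peak of signal 1175, and of iff-2 and F54C9.14, which share one of 1011. Those of ztf-7 and B0546.4 followed, at 911 and 771. The gene iff-2 encodes a translation factor of the eIF5A family. A further 3 of the 10 lay between genes. For rank 4 the nearest 5′ end was that of F07H5.13 (2972 bp away), and for rank 8 that of C30E1.4 (5835 bp). For rank 10 it was that of aakg-3 (4795 bp), a subunit gene of the energy sensor AMPK.

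Peaks were found mainly in promoters, introns and the space between genes, and rarely in coding sequence. Promoter windows held 3679 summits, 51.3% (95% interval 50.2 to 52.5), against 25.6% by random placement, a ratio of 2.0. The share was 51.4% in replicate 1 alone and 51.3% in replicate 2 alone. Coding exons held 2.06% against 18.7% by placement, 3′ UTRs 0.753% against 2.4%, and introns 17.1% against 27.4%. Intergenic sequence held 25.4% against 23.2%, and exons of noncoding RNAs or pseudogenes 2.87% against 2.15%. Each of these 6 shares differed from all 100 placements (permutation test by random placement, two-sided p = 0.0198, the smallest they can give). The share in 5′ UTRs outside promoter windows, 0.419%, lay within the placements (0.251% to 0.656%). Promoters held 59.1% of the strongest 1434 peaks and 46.3% of the weakest 1433. The median distance from a summit to the nearest annotated 5′ end was 729 bp, and 5.39% of summits were over 5000 bp away.

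**Figure D1:**
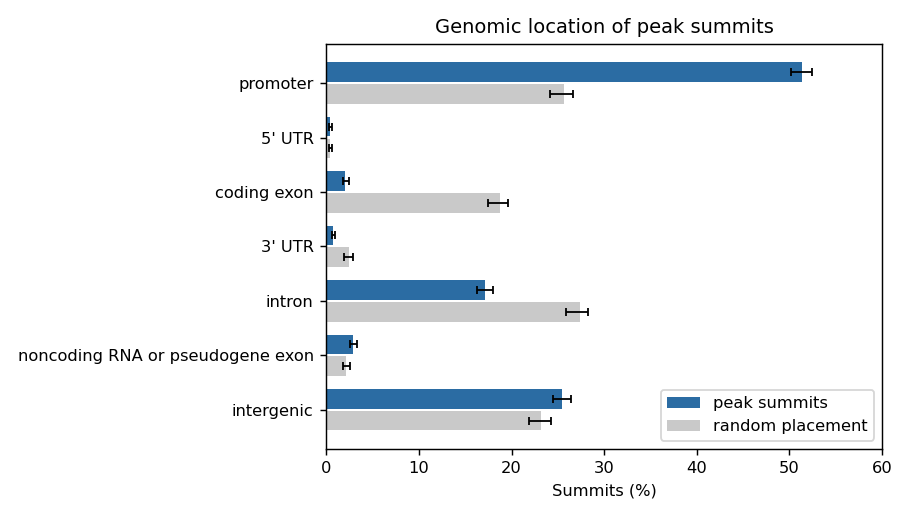
Share of the 7168 peak summits in each genomic class (blue, with 95% Wilson intervals) and the mean share over 100 random placements within chromosomes (grey, with their range); the horizontal axis is percent of summits. Promoter windows held 51.3% of summits against 25.6% by placement, and coding exons 2.06% against 18.7%.

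The X chromosome carried the most peaks per megabase. It held 1688 peaks, 95.3 per Mb, or 23.5% of peaks (95% interval 22.6 to 24.5), against 17.7% of nuclear sequence and 13.7% of protein-coding genes (exact binomial test against length, two-sided p = 3.51e-36). Its share was 23.03% in replicate 1 alone and 23.4% in replicate 2 alone. Chromosomes V and IV carried the fewest, with 54.8 and 57.6 per Mb. Promoter windows held 42.5% of X peaks, against 52.3% to 58.2% on the autosomes. Of the X genes, 24.4% had a promoter peak. The share was 26.9% on chromosome III, 23.7% on I, 18.2% on II, 17.6% on IV and 14.9% on V.

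Gene lists fixed beforehand asked which groups of genes have promoter peaks of tagged HLH-30 more often than other genes. Of 19973 protein-coding genes, 4012 (20.1%) had a promoter peak, and 808 peaks lay in windows of 2 or more genes. In the list test, 9 lists were occupied more often than other genes, 2 less often, and 7 did not pass. The p-values below are from Fisher's exact test, two-sided, adjusted over the 18 lists. Except in their own test, the other genes included 1291 chemoreceptor genes, of which 1.47% had a peak. No list was compared with genes matched on expression or open chromatin. A higher share therefore need not be particular to the process or to HLH-30.

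Autophagy genes had a promoter peak at 20 of 29, 69.0% (95% interval 50.8 to 82.7), against 20.02% of other genes (exact test, adjusted p = 7.44e-08). The share was 62.1% in replicate 1 alone and 72.4% in replicate 2 alone. After lgg-2 and lgg-1, the strongest were epg-7, a scaffold protein of selective autophagy, with a signal of 610 (chromosome X, 7334285 to 7334764), and atg-9, a membrane protein of early autophagosomes, with 514 (chromosome V, 349083 to 349387). The peaks at epg-7 and atg-9 each had a CACGTG within 50 bp of the summit, and those at lgg-1 and lgg-2 each had a CACATG. Of the 20 occupied autophagy genes, 12 had a promoter peak with either site. The strongest peak of all, in the intron of epg-9, had neither, nor did those of rank 2 to 5. Genes for lysosomal hydrolases and membrane proteins, the other main group tied to TFEB, had a peak at 20 of 52 (38.5%, interval 26.5 to 52.04, exact test, adjusted p = 0.00575). The strongest were scav-3, a lysosomal membrane protein of the scavenger receptor family (201), cpl-1, a cathepsin L (117), aagr-3, an acid alpha-glucosidase homologue (101.5), and cpr-4, a cathepsin B (100). The peaks at scav-3 and aagr-3 also lay in the window of a neighbouring gene, Y49E10.21 and drap-1 respectively. With the 3584 strongest peaks alone the lysosomal list was no longer distinguishable from other genes (13.5% against 11.7%, exact test, adjusted p = 0.747).

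The vacuolar ATPase, the proton pump that acidifies lysosomes, had a promoter peak at 10 of 21 subunit genes (47.6%, interval 28.3 to 67.6, exact test, adjusted p = 0.00838). Its strongest peaks were at vha-14 (195), vha-8 (149, shared with C17H12.2), vha-12 (113) and vha-15 (104.2). Genes of TOR and AMPK signalling, which sense nutrients and energy, were occupied at 9 of 20 (45%, interval 25.8 to 65.8, exact test, adjusted p = 0.0184). They included rheb-1, the GTPase that activates TOR complex 1 (281, shared with spk-1), the AMPK subunit gene aakb-2 (255, shared with Y47D3A.14), flcn-1, the folliculin gene (249, shared with F22D3.4), and lmtr-3, a subunit of the complex that tethers TOR to lysosomes (199, shared with atp-5). Lipid metabolism genes were occupied at 24 of 52 (46.2%, interval 33.3 to 59.5, exact test, adjusted p = 7.32e-05). The strongest were acs-2, an acyl-CoA synthetase (301), lbp-9, a lipid-binding protein (274), pmt-1, a methyltransferase of phosphatidylcholine synthesis (187), and nhr-49, a nuclear receptor of the fasting response (162). With the 3584 strongest peaks the lipid list stood at 25% against 11.6% (exact test, adjusted p = 0.0146). Genes of stress response and longevity were occupied at 23 of 43 (53.5%, interval 38.9 to 67.5, exact test, adjusted p = 4.41e-06). The strongest were the mitochondrial chaperone gene hsp-6 (398, shared with C37H5.5), the kinase gene akt-2 (260), the endoplasmic reticulum chaperone gene hsp-3 (246) and the transcription factor gene atf-4 (234, shared with an unnamed gene).

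Housekeeping groups were also occupied more often than other genes. Ribosomal protein genes had a peak in a promoter window at 70 of 81, 86.4% (95% interval 77.3 to 92.2, exact test, adjusted p = 9.86e-37), with 87.7% in replicate 1 alone and 88.9% in replicate 2 alone. The strongest were rpl-15 (609, shared with K11H12.8), rps-1 (491, shared with ifet-1), rpl-3 (452) and rps-19 (425, shared with hsr-9). Mitochondrial respiratory chain genes were occupied at 27 of 38, 71.1% (interval 55.2 to 83.0, exact test, adjusted p = 9.68e-11), led by cox-5A (388), ucr-2.1 (226, shared with nmat-1), sdha-1 (223) and cox-6B (210, shared with Y71H2AM.20 and nduc-2). Proteasome genes were occupied at 18 of 33, 54.5% (interval 38.0 to 70.2, exact test, adjusted p = 3.71e-05), led by rpn-13 (255), rpn-3 (225, shared with hsp-110), rpn-9 (189, shared with T06D8.9) and rpt-2 (160, shared with aps-1). When each summit was given to its nearest gene alone, these shares fell. They were 50.6% for ribosomal proteins, 55.3% for the respiratory chain and 45.5% for the proteasome. They then lay below autophagy genes (69.0%) and lipid metabolism genes (61.5%), and all 5 lists still passed (exact test, adjusted p at most 0.0138). This setting also counted summits outside promoter windows, which raised lipid metabolism from 46.2%, so this order of lists does not reflect neighbours' peaks alone. When only peaks with CACGTG or CACATG within 50 bp of the summit were used, an alternative added after the data were seen, 5 of the 9 lists no longer passed. These were ribosomal proteins (8.64% against 4.31% of other genes, exact test, adjusted p = 0.228), stress response and longevity (6.98% against 4.32%), the respiratory chain (2.63% against 4.33%), and the vacuolar ATPase, of which 0 of 21 genes had such a peak. The last was the proteasome, at 12.1% against 4.31%, a ratio close to that over all peaks (54.5% against 20.03%), so its call ended with only 4 of 33 genes occupied (exact test, adjusted p = 0.158).

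Chemoreceptor genes, which act in sensory neurons, were occupied at 19 of 1291 (1.47%, interval 0.944 to 2.29, exact test, adjusted p = 2.29e-98). Among those with a peak were srh-2 (344), srv-7 (221) and srh-17 (108). None of the 20 pharynx markers had a promoter peak (95% upper bound 16.11%, exact test, adjusted p = 0.0352). This call was lost with the nearest gene only (5.0%, exact test, adjusted p = 0.0793), the narrower window (adjusted p = 0.0988) and the 3584 strongest peaks (adjusted p = 0.285). Markers of the other tissues did not pass the test. Intestine markers were occupied at 6 of 25 (24%, exact test, adjusted p = 0.725), among them act-5 (65.7), ifp-1 (59.3), elt-2 (52.7) and ftn-1 (52.6). Neuron markers were occupied at 7 of 30 (23.3%, exact test, adjusted p = 0.725), among them snb-1 (202) and sbt-1 (129, shared with num-1). They passed when each summit was given to its nearest gene at any distance (46.7%, exact test, adjusted p = 0.0156). Body muscle markers were occupied at 4 of 25 (16%, exact test, adjusted p = 0.804), among them unc-60 (94.7, shared with F53E2.2). Epidermis and cuticle markers were occupied at 10 of 31 (32.3%, exact test, adjusted p = 0.156), among them ajm-1 (88.4). Germline markers were occupied at 3 of 35 (8.57%, exact test, adjusted p = 0.141), among them gld-2 (258), and passed as lower with the wider window (adjusted p = 0.0284). Immune effectors were occupied at 13 of 50 (26%, exact test, adjusted p = 0.374), with the strongest peaks at the transcription factor genes zip-2 (340) and atf-7 (151). Of 38 bHLH and leucine-zipper partner genes, 6 had a peak (15.8%, exact test, adjusted p = 0.725), among them hlh-11 (380), mdl-1 (253), mxl-3 (161) and mml-1 (150). The genes mdl-1, mml-1 and mxl-3 encode members of the worm's Max-like network. The lists that did not pass hold 25 to 50 genes, and their intervals do not exclude moderate differences.

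**Figure D2:**
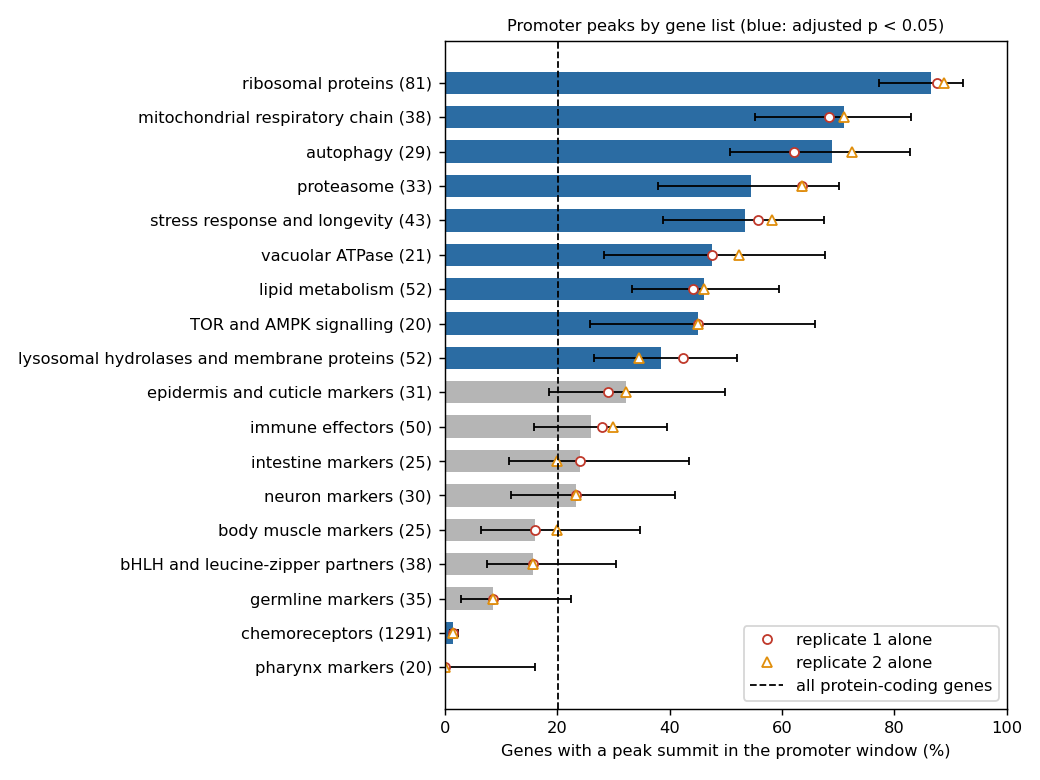
Share of each gene list (number of genes in brackets) with a peak summit in a promoter window, in percent, with 95% Wilson intervals; open circles and triangles give the strongest 7168 peaks of replicate 1 and replicate 2 alone, and the dashed line marks all protein-coding genes (20.1%). Blue bars mark lists past the test; with summits counted for every window they fall in, ribosomal protein genes (86.4%) lie highest, chemoreceptors (1.47%) and pharynx markers (0%, no bar) lowest.

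Among 175 gene classes tested without selection, 27 were occupied more often than other genes and 33 less often (Fisher's exact test, adjusted over the classes). The classes rpl and rps led, with 41 of 47 and 27 of 31 genes. They were followed by nucleoporins (npp, 17 of 26, 65.4%, exact test, adjusted p = 9.55e-06), lin genes (24 of 47, 51.1%), nuclear hormone receptors (nhr, 85 of 269, 31.6%), translation initiation factors (eif, 15 of 25, 60%) and aldehyde dehydrogenases (alh, 10 of 13, 76.9%). The autophagy class atg stood at 8 of 12 (66.7%, exact test, adjusted p = 0.00326), and vacuolar sorting genes (vps) at 16 of 31 (51.6%). Less often occupied were C-type lectins (clec, 7 of 240, 2.92%, exact test, adjusted p = 2.11e-13), collagens (col, 8 of 156, 5.13%) and several chemoreceptor classes, such as srh (6 of 220, 2.73%) and str (4 of 193, 2.07%). The strongest promoter peaks of clec genes were at clec-140 (183, shared with hmg-11) and clec-126 (140), and those of str genes at str-176 (72.0) and str-101 (52.4). In replicate 1 alone, 31 classes were more often occupied, 24 of them among the 27, and 30 were less often occupied. In replicate 2 alone these numbers were 21, 20 and 32. With the 3584 strongest peaks, 18 classes were more often occupied, 17 of them among the 27, and 17 were less often occupied. With each summit given to its nearest gene alone, 20 classes were more often occupied, of which only 15 were among the 27. With only peaks that hold CACGTG or CACATG, 3 classes were more often and 2 less often occupied, out of 864 occupied genes.

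The sequence under the summits was examined for the E-box, the site of bHLH factors. The palindrome CACGTG was present within 50 bp of 792 of 7168 summits, 11.0% (95% interval 10.3 to 11.8), against 2.04% of the control windows, a ratio of 5.42 (exact McNemar test, adjusted p = 3.42e-114 over the 10 E-boxes). CACATG was present at 1087 summits, 15.2% (interval 14.4 to 16.01), against 2.96%, a ratio of 5.13 (exact McNemar test, adjusted p = 2.41e-152). The other 8 E-boxes had ratios from 1.03 to 1.9. CACGTG was at 10.8% and CACATG at 14.3% of the peaks of replicate 1 alone, and at 10.5% and 14.1% of those of replicate 2 alone. Both sites were most frequent at the summit: the central 20 bp held 30.6 CACGTG and 43.8 CACATG sites per 1000 peaks. One or both were found at 25.3% of summits. Of the 17729 CACGTG sites in the nuclear genome, 850 (4.79%) lay within 50 bp of a summit. The bases beside the site also differed from control windows. TCACGTGA made up 13.4% of the CACGTG sites at summits and 6.38% of those in control windows on both sides (Fisher's exact test, adjusted p = 0.0149), while CCACGTGG made up 5.26% and 16.7% (adjusted p = 5.17e-07). TCACATGA made up 19.2% of the CACATG sites at summits and 13.4% in control windows (Fisher's exact test, adjusted p = 0.03).

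**Figure D3:**
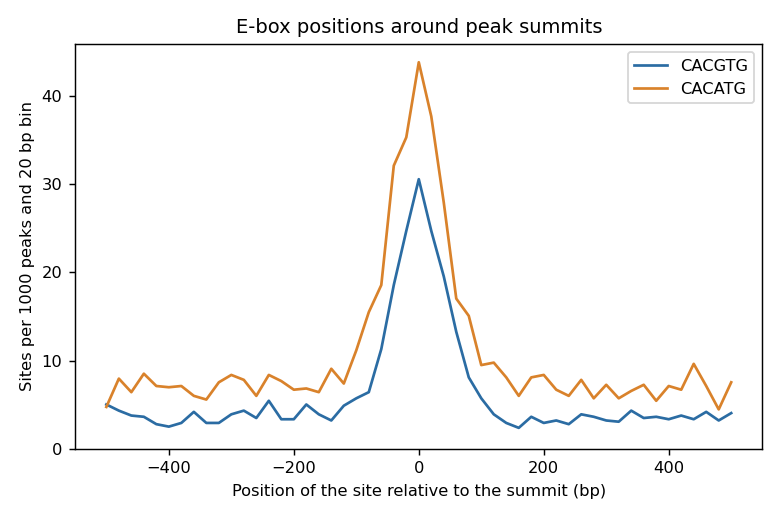
Number of CACGTG (blue) and CACATG (orange) sites per 1000 peaks in bins of 20 bp, plotted against the distance of the site from the peak summit in bp. Both are highest at the summit, at 30.6 and 43.8 sites, and fall to 5.72 and 9.49 in the bin centred 100 bp to the right.

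Stronger peaks held CACGTG more often. Its share fell from 16.18% (95% interval 14.4 to 18.2) in the strongest 1434 peaks to 6.84% (5.64 to 8.26) in the weakest 1433, a difference of 9.34 percentage points (Fisher's exact test, two-sided, p = 3.26e-15). The control windows stayed between 1.74% and 2.3%. CACATG fell from 18.97% to 13.4% (Fisher's exact test, p = 5.98e-05). Either site was at 33.7% of the strongest 1434 peaks, so most of them held neither.

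**Figure D4:**
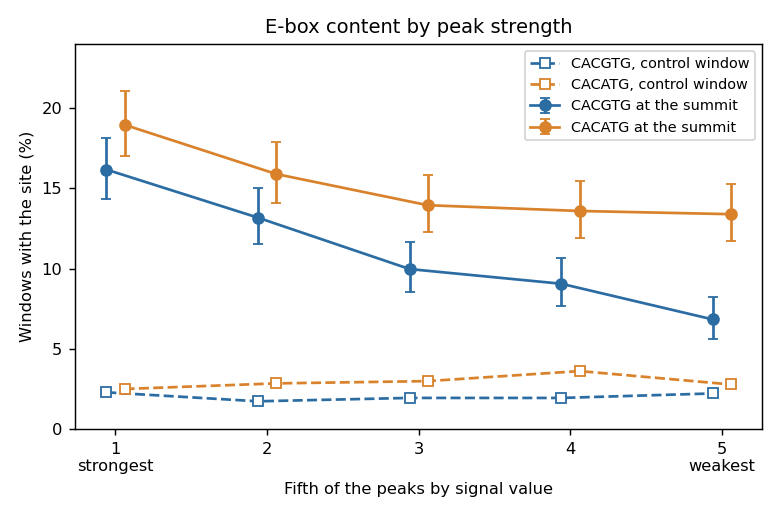
Share of windows with CACGTG (blue) or CACATG (orange), in percent, in each of 5 equal parts of the 7168 peaks by signal value, from strongest to weakest; filled circles are summit windows of 50 bp on each side with 95% Wilson intervals, open squares the control windows 500 bp to the left. CACGTG falls from 16.18% to 6.84% and CACATG from 18.97% to 13.4%.

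The tagged gene and unc-119, the gene mutated in the strain, were looked at separately, since a transgene can add copies of its own sequence. No peak lay in the promoter window of hlh-30 (chromosome IV, 4014793 to 4034951). The only peak within 20 kb was at the promoter of pcn-1, with a signal of 141 and rank 1061. At unc-119 (chromosome III, 10902641 to 10908935), 2 peaks lay in introns, with signal values of 84.4 and 52.5, and none in the promoter. These counts did not differ from windows around 10000 random genes, which held 4.26 and 3.29 peaks on average (permutation test over random genes, two-sided p = 0.488 and 0.947).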

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

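This test was chosen after the thresholded peaks had been analysed. The pooled list holds 22832 entries below the authors' threshold, which no comparison of the report uses, and they carried CACGTG more often than their own control windows. CACGTG lay within 50 bp of 3.81% of their summits (95% interval 3.57 to 4.07) and in 1.75% of the control windows, a ratio of 2.18 (exact McNemar test, p = 8.64e-42). Entries that overlap a thresholded peak were not removed, and the 30000 pooled entries merge to 26593 regions. Part of the difference may therefore come from sites already counted at thresholded peaks. The share was 6.5% at ranks 7169 to 10000, 4.98% at 10001 to 15000, 3.52% at 15001 to 20000 and 3.06% at 20001 to 25000. At ranks 25001 to 30000 it was 2.16% against 1.78% (exact McNemar test, p = 0.193). Promoter windows held 41.7% of the summits in the first of these ranges and 25.4% in the last, where random placement of the thresholded peaks gave 25.6%.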

How the results depend on the processing

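Using only peaks with CACGTG or CACATG, and all alternatives for CACATG, were chosen after the data were seen. Of the planned recalculations 162, and of the added ones 16, left direction and call (or a count within 1.5 times) as reported. Among the other planned ones, 11 changed sign, 4 lost a call, 2 gained one and 4 counts moved further. Among the other added ones, 4 changed sign, 4 lost a call and 4 counts moved further. The 16 unchanged include all 6 for CACATG. No alternative changed the direction or call of peak number, replicate overlap (72.0% to 81.7%), promoter share (21.6 to 29.3 percentage points above placement), both E-boxes, the fall of CACGTG with strength, the X share, the hlh-30 region, or the autophagy, lipid, TOR and AMPK, immune and chemoreceptor lists. Values below are percentage points against other genes, and the cause was not tested unless given. The lipid list ranged from 11.1 (peaks with either site) and 13.4 (3584 strongest peaks) to 38.2 (nearest gene alone), against 26.1 as reported, and chemoreceptors from -24.5 to -4.29, against -19.9. With the 3584 strongest peaks, which leave fewer occupied genes, the lysosomal list fell to 1.79 and pharynx markers to -11.7 (neither passed), while 18 classes were higher and 17 lower. In lists that had not passed, the sign changed for bHLH genes (4.12), intestine (-7.69), body muscle (0.325) and epidermis markers (-2.0). The narrower window gave 0.645 for bHLH genes, 0.856 for body muscle and -15.2 for pharynx markers, which no longer passed. The wider window gave 6.1 for body muscle and -17.4 for germline markers, which then passed. The nearest gene alone lowered ribosomal proteins from 66.6 to 27.3, the respiratory chain from 51.1 to 31.8 and the proteasome from 34.5 to 22.01, which all still passed. It gave 0.208 for bHLH genes, 8.53 for body muscle, -18.5 for pharynx markers, which no longer passed, and 23.2 for neuron markers, which then passed. Each of the 3584 strongest peaks, the narrower window and the nearest gene left 1 list lower in place of 2. With either replicate left out, intestine markers ranged from -0.0271 to 3.84, and no other list changed sign or call. Within 10 kb, unc-119 had 0.125 peaks more than random windows. Peaks with either site alone left 4 lists higher and 1 lower, 3 classes higher and 2 lower, out of fewer occupied genes. The vacuolar ATPase (-4.33), respiratory chain (-1.7), bHLH (3.58) and neuron lists (-0.994) changed sign, and ribosomal proteins (4.33), proteasome (7.81), stress response (2.66) and pharynx markers (-4.33) no longer passed. For the proteasome this was 12.1% against 4.31% of other genes, where all peaks gave 54.5% against 20.03%, so the ratio held while the number of occupied genes fell. Without read counts, no result could be tested against depth. No paired analysis was possible because there is only 1 group.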

Other observations

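The noncoding RNA comparison, the tests of E-boxes in ribosomal protein promoter peaks, the second test on the X chromosome, the base composition test and the other sequence elements below were chosen after the results they concern were seen.

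Summits lay near genes for tRNAs, snoRNAs and snRNAs more often than random placement gave, and near those for piRNAs less often. Placement was compared on the share of summits, and counts of genes were not compared with it. A summit lay within 200 bp of 329 of 612 tRNA genes (53.8%), of 102 of 346 snoRNA genes (29.5%) and of 27 of 129 snRNA genes (20.9%). Such sites held 4.2%, 1.44% and 0.446% of all summits, 13.9, 7.86 and 7.71 times the mean of 100 random placements (permutation test by random placement, two-sided p = 0.0198 each, the smallest they can give). Genes for piRNAs, the largest class with 15363, held 0.977% of summits against 2.72% by placement, a ratio of 0.359. Pseudogenes were low too, with 25 of 2128 near a summit (1.17%), and held 0.0897 times as many summits as placement gave. Above placement, by smaller ratios, were the classes ncRNA (3.78), lincRNA (2.27), miRNA (2.13) and antisense RNA (1.86), with permutation p of 0.0198 for the first pair and 0.0396 for the rest. The 301 peaks near tRNA genes had CACGTG in 1.66% of cases (95% interval 0.712 to 3.83), against 9.7% of all promoter peaks, but either CACGTG or CACATG in 19.9%, against 21.5%.

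Other sequence elements were also enriched at summits. In the scan of 2080 hexamers, 920 were more frequent at summits than in control windows and 593 less frequent (exact McNemar test, adjusted p under 0.05). By p over both directions together, CACATG and CACGTG ranked 12 and 24. Hexamers ranked above them included some less frequent at summits, such as AAAATT at rank 1 (14.6% against 44.8%). GAGAGA lay at 24.1% of summits against 5.78% of control windows. The octamer TGCGTCTC, put together from overlapping hexamers of the scan, lay at 7.88% against 0.502%, 15.7 times as often, and its share fell from 13.04% in the strongest 1434 peaks to 4.54% in the weakest 1433. It lay at 5.19% of the summits with CACGTG or CACATG and 8.79% of those without (Fisher's exact test, p = 4.09e-07), and GAGAGA at 18.2% and 26.1% (Fisher's exact test, p = 6.03e-12). Promoter peaks of ribosomal protein genes held GAGAGA at 10.1% and TGCGTCTC at 4.35%, against 23.4% and 8.92% of all promoter peaks. These last differences were not tested.

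Ribosomal protein promoters were occupied at 86.4%, or 50.6% with each summit given to its nearest gene alone, but few of their peaks held CACGTG or CACATG. Either site was at 10.1% of their 69 promoter peaks (95% interval 5.0 to 19.5), against 42.6% of the 54 promoter peaks of autophagy, lysosomal and vacuolar ATPase genes (Fisher's exact test, p = 4.2e-05), 21.7% of all other promoter peaks (Fisher's exact test, adjusted p = 0.0354), 20% for the proteasome, 3.45% for the respiratory chain and 4.91% in control windows. The pool was mixed, since a peak with either site lay at 12 of 20 occupied autophagy genes and 10 of 20 lysosomal genes, but at 0 of 10 vacuolar ATPase genes. Crowded promoters are argued against as the whole cause, since random lists with the same upstream distances were occupied at 24.2%, but the fall to 50.6% (23.4% of other genes) leaves open that neighbours' peaks make up part of the pattern. Signal at open, highly transcribed loci that does not need the factor's own site is consistent with the 10.1%, and recruitment of HLH-30 through other proteins, which was not tested, would give the same; both stay open, because the control library and worms without the tagged factor were not analysed here.

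At the density of the autosomes the X chromosome would hold 1176 peaks, so 30.3% of its 1688 peaks were surplus. More noncoding sequence is argued against as the whole cause, since X holds 18.8% of the sequence outside coding exons, below the 22.6% lower bound of its share of peaks. A surplus with no more CACGTG than control windows is argued against. CACGTG was present in 11.0% of X peaks (95% interval 9.56 to 12.5) and 11.1% of autosomal peaks. The mixture implied by such a surplus would give 8.34%. Weak entries can hold more than control windows do. Those just below the threshold (ranks 7169 to 10000) had CACGTG at 6.5%, against 1.87% of their own control windows. Whether these entries are background or weaker sites is unknown, so they give no rate for background. A surplus of such weak entries was not tested. Peak location was left out too, and CACGTG was at 9.7% of promoter, 13.5% of intron and 11.6% of intergenic peaks. The X share was 19.5% of promoter peaks, 27.01% of intron peaks and 26.7% of intergenic peaks. No biological explanation was tested, and the coverage of the control alignment on X was not analysed here.

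CACATG and the palindrome CACGTG had similar ratios of summit to control, 5.13 and 5.42, whose difference was not tested. Base counts alone are argued against. Hexamers with the bases of CACGTG had a median ratio of 1.23 between summit and control, and those with the bases of CACATG 1.06. None reached the ratio of its site, although CGTGAC, which can overlap CACGTG, came close (5.125 against 5.42). These hexamers need not keep the CG pair of CACGTG. Other hexamers with CG had higher or lower ratios than CACGTG, such as CACGCG (6.66) and CGCGCG (4.75). A general rise of CG at summits was not tested for CACGTG. Clustering of the sites is argued against as well, since CACATG had a ratio of 5.6 in the 6376 peaks without CACGTG. Both sites occurred in 68 peaks where independence would give 120 (Fisher's exact test, p = 8.49e-09). A candidate explanation is that CACATG is bound in its own right, by HLH-30 or by another bHLH factor at the same sites, which was not tested.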
